A study of Mus musculus with 12 samples.

How the data were processed

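Total RNA from 12 oral tumours of C57BL/6 × FVB F1 mice was measured on Affymetrix Mouse Gene 2.0 ST arrays read at the level of exons, 1 array per tumour. The mice had received tamoxifen by intraperitoneal injection. Per the labels, 6 tumours came from mice written KR and expressed RAS. The other 6 came from mice written KHR and expressed RAS together with a transgene written iHPV, of which a further label names HPV E6. What these letters stand for, whether other viral genes were carried, and the sex, age and litter of the animals are not given in the sources used here. Nothing in the labels says that the 6 tumours of a group came from separate animals, so the p-values measure the spread between these samples.

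The deposited values were log2 intensities, 1 value per probeset and array, for 269751 probesets. Partek is named in the submitters' processing notes, with no version. The background correction, the normalization and the genome build are not given in the sources used here, and the base of the logarithm was taken from the range of the values. The arrays' medians lay between 5.62 and 5.75, and the quartiles were close without being identical. The number of arrays, 6 against 6, limits the precision. The highest correlation between any 2 arrays was 0.97, so no array was a copy of another.

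Probesets were named through GEO's platform annotation, and older symbols were updated through the synonyms of the RefSeq table of the assembly GRCm38.p6. Of the probesets, 233753 had 1 gene symbol, 5106 had several and 30892 had none. Of the 23152 symbols, 20875 were current, 2247 were updated through a synonym and 30 matched no entry and were kept as given. The value of a gene on an array was the median of the log2 values of its probesets with 1 symbol, which gave 23102 genes with a median of 8 probesets; 2303 genes rested on 1 probeset. Genes without such a probeset are not analysed here. No filter on dim genes was set. Changes are KHR minus KR on the log2 scale, and the order of genes in that RefSeq table was used only to find the neighbours of Stag3.

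Genes were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with all 12 arrays and no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes with a threshold of 0.05. For 33 gene lists, camera with a preset correlation of 0.01 tested whether a list moved against the other genes, adjusted over the lists; camera with an estimated correlation and fry were run beside it. Unless a sentence says otherwise, an adjusted p of a list is camera's with the preset correlation. The mean of a list is the mean over its measured members on an array, and its error is the SE of the difference between groups of 6. The first 3 principal components of all genes were tested by an exact permutation test, two-sided, for which the smallest p that 6 against 6 arrays can give is 0.0021645. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

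The groups, tests, gene lists, the rule for the genes named and the alternatives were fixed before the data were examined. The rule named, in each direction, the 12 genes with the largest change among those past the threshold whose mean level was above the median of all genes (4.98); of each list, the 4 members with the smallest p where the list passed and the 2 with the smallest p where it did not; and a fixed set of RAS, Rb, p53, cycle and keratin genes together with Xist, of which those not listed are not analysed here. Some members chosen by the rule that did not pass are not written out. Genes named outside this rule are said to be so. The lists covered cell cycle and viral carcinogenesis (E2F S-phase targets, G2M and mitosis, core of the Rb pathway, genes higher in human HPV-positive head and neck cancer, p53 targets, RAS and MAPK output), keratinocyte states (basal, squamous differentiation, stress), immune genes (interferon response, antigen presentation, inflammatory cytokines, T and NK cells, B and plasma cells, macrophages, neutrophils, mast cells, dendritic and Langerhans cells), other cell types (fibroblast matrix, invasion and EMT, endothelium, skeletal muscle, salivary gland, adipocytes, Schwann cells, hair follicle, sebaceous gland, blood) and metabolism or signalling (hypoxia and glycolysis, Nrf2, unfolded protein response, oxidative phosphorylation, Notch). A list of sex-linked transcripts served only to read animal sex and was not among the 33.

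The alternatives were other summaries of probesets (mean, median polish, a test per probeset), other scalings (quantile normalization, array medians subtracted), filters on dim genes and on genes with fewer than 3 probesets, eBayes with trend and robust, array weights, the replicate number as a block, the Xist level as a covariate, stricter thresholds, an exact rank test, other list tests and leaving out each array in turn. Chosen after seeing the data were the mean of the skeletal muscle list as a covariate, animal sex as a factor, leaving out KR 1 and KHR 5 together, and the HPV-positive list without members shared with the E2F list, without Stag3, and without both. The germline list described among the further observations was also compiled then, and tested with and without the genes that prompted it. The steps were tested on simulated data with the spread of these 23102 genes: 39.4% of genes changed by 0.5 on the log2 scale were recovered, 89.6% of those changed by 1 and 97.0% of those changed by 2. In that simulation 6.55% of the calls were false, and the 1 shifted list was the only list called. Genes were drawn there independently of one another, so it cannot show how often lists of correlated genes are called falsely.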

Results

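The series compared oral tumours that expressed RAS alone (KR, n = 6) with oral tumours that expressed RAS and a human papillomavirus (HPV) transgene (KHR, n = 6), all from tamoxifen-treated mice. It asks how the viral transgene changes the expression profile of a RAS-driven oral tumour. Each tumour gave 1 array, and the array medians of all probesets lay between 5.62 and 5.75 on the log2 scale. Xist, the transcript of the inactive X chromosome, was high on 2 of 6 KR arrays and 4 of 6 KHR arrays, so animal sex was uneven between the groups. The mean of 30 skeletal muscle genes was 5.77 ± 0.42 in KR tumours and 6.20 ± 0.74 in KHR tumours (SD, n = 6 each), with KHR 5 highest at 7.31.

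The tumours parted by genotype along the main axis of their expression. Component 1 held 25.7% of the variance of all genes, and the group accounted for a share of 0.73 of the variance of its scores. Scores averaged -19.98 ± 11.98 in KR tumours and 19.98 ± 14.42 in KHR tumours (SD, n = 6 each; exact permutation test, two-sided, p = 0.0021645, the smallest it can give, adjusted p = 0.00649). Components 2 and 3, with 13.1% and 11.3% of the variance, did not separate the groups (exact permutation p = 0.160 and 0.859).

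**Figure D1:**
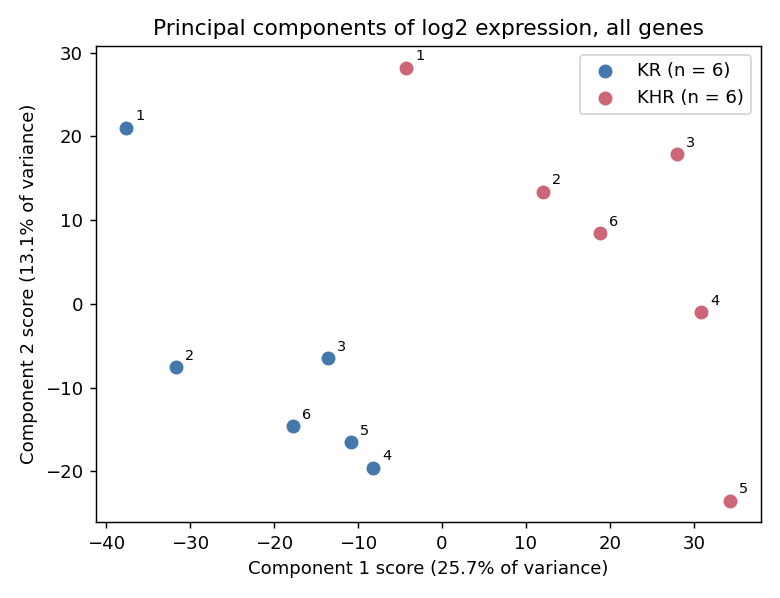
Scores of the 12 tumours on components 1 and 2 of the log2 expression of all genes, with the share of variance on each axis and the replicate number beside each point. All 6 KR tumours lie at negative scores on component 1, and 5 of the 6 KHR tumours lie at positive scores, with KHR 1 at -4.25.

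Stag3, the cohesin subunit of meiotic chromosomes, rose in KHR tumours from 4.35 ± 0.12 to 8.72 ± 0.23 (SD, n = 6 each), a log2 change of 4.37 ± 0.11 (SE; adjusted p = 2.52e-11). Zcwpw1, a reader of histone marks at meiotic recombination sites and a near neighbour of Stag3 in the assembly GRCm38.p6, rose by 3.31 ± 0.12 (adjusted p = 1.18e-09). The labels do not say which DNA flanks the transgene. The germ cell genes Tdrd1, of the piRNA pathway, and Rbm46, which encodes an RNA-binding protein, rose by 2.84 ± 0.21 and 2.69 ± 0.31. Ina and Nes, both intermediate filament genes of neural cells, rose by 3.50 ± 0.18 and 2.09 ± 0.16. Ulbp1, which encodes a ligand of the NKG2D receptor of NK cells, rose by 2.89 ± 0.21, and the MHC class I-like gene Mill1 rose by 2.22 ± 0.27. The proton pump gene Atp12a rose by 3.36 ± 0.45, carbonic anhydrase Car2 by 2.48 ± 0.25, the cornified envelope gene Sprr4 by 2.43 ± 0.39 and AA467197 by 2.59 ± 0.38, Sprr4 from 1 probeset. These 12 had adjusted p-values up to 0.00349. The KR means of Stag3, Ina, Zcwpw1, Tdrd1 and Rbm46 lay below the median level of all genes (4.98), and with no detection call the sizes of these 5 changes are not exact.

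Among the 12 genes named for the largest falls, Bpifa5, of a family of secreted antimicrobial proteins, changed by -3.49 ± 0.60 (SE; adjusted p = 0.00549). Its KR values were spread widely, at 7.82 ± 1.63 against 4.33 ± 0.55 in KHR tumours (SD, n = 6 each), a level below the median of all genes, so the size of its change is not exact either. Pax9, a transcription factor of oral and oesophageal epithelium, changed by -1.86 ± 0.24, and the signalling genes Wnt7b and Bmp6 by -1.77 ± 0.18 and -1.41 ± 0.16. The monooxygenase gene Fmo2 and the aldehyde oxidase gene Aox4 changed by -1.86 ± 0.20 and -1.38 ± 0.20. Slc6a19, an amino acid transporter, changed by -1.60 ± 0.17, the protease-like gene Prss35 by -1.52 ± 0.31 and the kinase gene Wnk4 by -1.47 ± 0.20. Ces1h, Ces2f and Defa-ps12 changed by -2.03 ± 0.37, -1.63 ± 0.23 and -1.68 ± 0.13, but their families hold near-identical copies, so which member changed is uncertain. The highest adjusted p among these 12 was 0.0158, for Prss35. With the mean over probesets in place of the median, the changes of AA467197, Wnt7b and Prss35 were 1.66, -0.98 and -1.01, all still past the threshold (Wnt7b -1.08 with median polish).

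Over all genes, 863 of 23102 differed between the groups, 625 of them higher and 238 lower in KHR tumours (limma, adjusted p under 0.05). Among these, 139 were at least 2-fold higher and 41 at least 2-fold lower. All KHR arrays lay above or below all KR arrays for 617 genes, which is 2.67% against 0.216% by chance. Leaving out KR 2 or KHR 4 gave 531 and 523 genes, with 131 and 123 lower, and leaving out KR 6 gave 151 lower. With quantile normalization 56.8% of the calls were higher against 72.4% here, and the mean over probesets gave 1445 genes, the Xist level as a covariate 555, and an exact rank permutation test 0 after adjustment (3051 at an unadjusted p under 0.05). The rank test can give no p below 0.0021645, which too few genes reached for any to pass after adjustment.

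**Figure D2:**
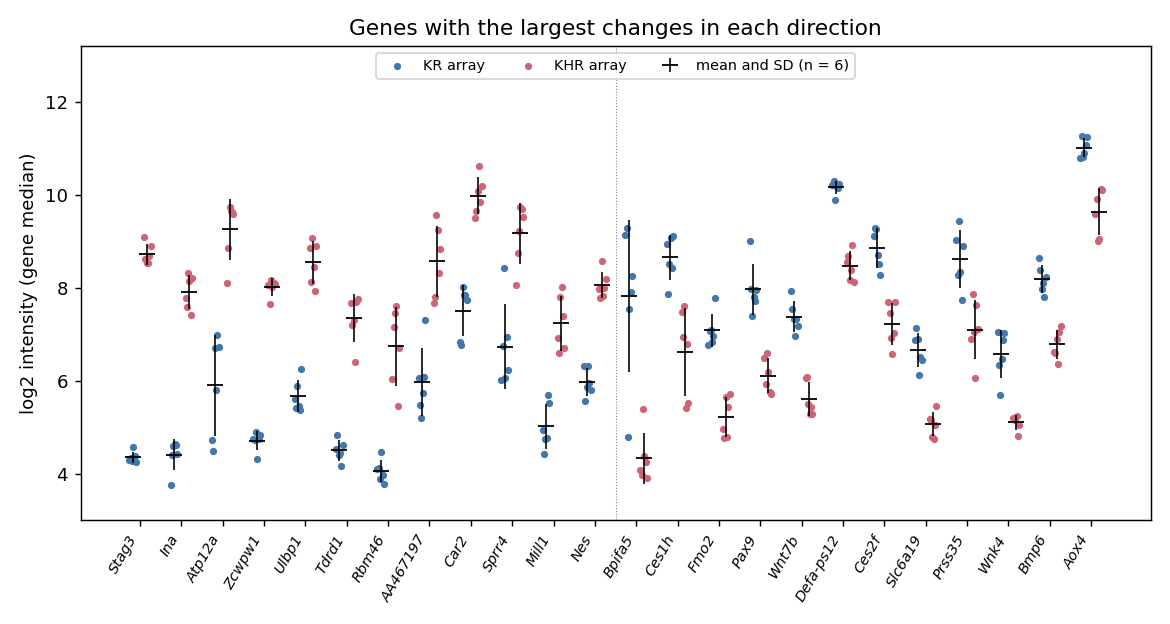
Log2 intensity of the 24 genes with the largest changes, 12 higher (left) and 12 lower (right) in KHR tumours, as points for each array with the mean and SD (n = 6 per group). Stag3 lies near 4.35 on every KR array and near 8.72 on every KHR array, while Bpifa5 is spread widely among the KR arrays.

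Genes of DNA replication rose together in KHR tumours. Of 44 measured E2F S-phase targets, 33 rose and none fell, and all 44 were higher when adjusted over the list alone; the list mean rose from 7.26 ± 0.07 to 8.14 ± 0.14 (SD, n = 6 each). Prim1, the primase subunit, rose by 1.62 ± 0.09 (SE; adjusted p = 3.4e-07), the replicative helicase genes Mcm6, Mcm4 and Mcm7 by 1.30 ± 0.10, 1.11 ± 0.10 and 1.07 ± 0.13, and Rrm1, of ribonucleotide reductase, by 0.99 ± 0.10. Pcna, the sliding clamp, rose by 0.93 ± 0.10 (adjusted p = 0.000379). E2f1 itself was higher by 0.47 ± 0.12 and just missed the threshold (adjusted p = 0.0523), and passed it without KHR 2 (adjusted p = 0.0134; up to 0.108 on leaving out others). The list moved against the other genes (adjusted p = 2.67e-49; adjusted p = 0.000453 with an estimated correlation).

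Mitotic genes rose as well, by less. Of 33 measured G2M and mitosis genes, 22 rose and none fell (29 higher adjusted over the list alone), with a mean change of 0.61 ± 0.07 (adjusted p = 1.5e-28; adjusted p = 0.00652 with an estimated correlation). The cyclin Ccnb2 rose by 0.81 ± 0.11, the mitotic kinases Ttk and Aurkb by 0.99 ± 0.15 and 0.64 ± 0.10, the kinesin Kif2c by 0.75 ± 0.12 and the proliferation marker Mki67 by 0.66 ± 0.13 (adjusted p = 0.00998).

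The list of genes higher in human HPV-positive head and neck cancers moved up in the KHR tumours, though not every member did. Of 20 measured, 11 rose and none fell (14 higher and 2 lower adjusted over the list alone), with a mean change of 0.79 ± 0.05 (adjusted p = 6.26e-16; adjusted p = 0.000453 with an estimated correlation). Cdkn2a went the other way, at -0.81 ± 0.31 (adjusted p = 0.210), and was 1 of the 2 lower over the list alone. The members with the smallest p were Stag3, Prim1, the DNA ligase Lig1, at 0.94 ± 0.08, and Mcm7. Without Stag3 the mean was 0.60 over 19 genes (adjusted p = 1.03e-12; adjusted p = 0.000772 with an estimated correlation). Without the members shared with the E2F list, 13 genes were left, of which 5 rose. Their mean change was 0.67 and their median 0.47 (adjusted p = 1.31e-06, and adjusted p = 0.00411 with an estimated correlation). Stag3 raised that mean: without it as well, the mean of 12 genes was 0.36 (adjusted p = 0.000395; adjusted p = 0.0192 with an estimated correlation), and 4 rose. Those 4 were the DNA ligase Lig1, Cenpk (1.16), Kcns1 (1.13) and Smc1b (0.70). Cdkn2c, of the Rb pathway list, was also left, at 0.36 and not past the threshold. All of these except Lig1 are named outside the rule. Leaving out the shared members thus did not remove every gene of DNA replication or of the cell cycle. The E2F, G2M and HPV-positive lists were the only ones of the 33 that passed with an estimated correlation.

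Among 26 core genes of the Rb pathway, 7 rose and 1 fell (10 higher and 3 lower adjusted over the list alone). All that rose except Cdk2 are also members of the E2F list, so the rise of this list is not independent of that one. The kinase gene Cdk2 rose by 1.00 ± 0.12, its partners Ccne1 and Ccne2 by 1.27 ± 0.16 and 1.55 ± 0.25, and the repressor E2f7 by 1.11 ± 0.22. Ccnd1, the cyclin D1 gene, changed by -0.52 ± 0.12 (adjusted p = 0.0346), a call that was lost on leaving out any of 9 arrays (adjusted p up to 0.0778) and with the mean over probesets (-0.34, adjusted p = 0.0998). Rb1 differed by 0.19 ± 0.12 (adjusted p = 0.489). Cdkn2a, the p16 and p19 gene, stood at 6.32 ± 0.77 in KR and 5.51 ± 0.45 in KHR tumours (SD, n = 6 each; adjusted p = 0.210 in limma); without KR 4, its change of -1.10 passed (adjusted p = 0.0117; up to 0.370 on leaving out others). The list mean was 0.29 ± 0.05 higher (adjusted p = 0.000377; adjusted p = 0.102 with an estimated correlation).

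The targets of p53, the tumour suppressor that HPV E6 is known to send to degradation, showed no shift in a shared direction. Of 29 measured, 1 rose and none fell (2 higher and 1 lower adjusted over the list alone), and the mean change was 0.03 ± 0.06 (adjusted p = 0.943), with the test's sign opposite to that of the mean and the median of 0.01. Cdkn1a and Mdm2, both classical targets, differed by 0.08 ± 0.17 and 0.03 ± 0.16 (adjusted p = 0.884 and 0.957). Tigar, a regulator of glycolysis, rose by 0.42 ± 0.10 (adjusted p = 0.0362), which was lost on leaving out any of 10 arrays (adjusted p up to 0.0752) and with median polish (0.21, adjusted p = 0.101). Zmat3 differed by -0.62 ± 0.17 (adjusted p = 0.0575) and passed without KR 4 (adjusted p = 0.0245; up to 0.129 on leaving out others). For the p53 list the mixed test of fry, for changes in either direction, passed (adjusted p = 0.00144). It also passed for many lists without a shared shift, such as stress keratinocytes (adjusted p = 1.65e-05) and the unfolded protein response (0.0378). It did not pass for others, such as endothelium (0.601), so passing does not set the p53 list apart. Among 24 genes of RAS and MAPK output, 1 rose and 1 fell (2 and 2 adjusted over the list alone). The RAS and MAPK list showed no shift in a shared direction (mean change 0.06 ± 0.10, adjusted p = 0.912), while the mixed test of fry passed (adjusted p = 0.00511). Dusp6, a feedback phosphatase of ERK, rose by 0.79 ± 0.16 (adjusted p = 0.0131), and Ccnd1 was the member that fell.

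Squamous differentiation genes changed in both directions. Of 45 measured, 2 rose and 7 fell (2 higher and 10 lower adjusted over the list alone). Klk7, a protease of the shedding epidermis, and Ivl, the cornified envelope protein involucrin, rose by 1.09 ± 0.15 and 1.59 ± 0.30. Krt13, the keratin of the oral suprabasal layers, changed by -1.26 ± 0.22 (adjusted p = 0.00571), and Ppl, the cornified envelope protein periplakin, by -0.42 ± 0.09 (adjusted p = 0.0204; 0.0529 without KHR 4). The list mean changed by -0.08 ± 0.04 (adjusted p = 0.00529; -0.05 without KHR 2, adjusted p = 0.0322), a call lost with an estimated correlation (adjusted p = 0.298), with quantile normalization (adjusted p = 0.126) and with fry (adjusted p = 0.0652). The 17 basal keratinocyte genes showed no shift in a shared direction (mean change -0.01 ± 0.06, adjusted p = 0.915). For them fry gave the opposite sign, as did the median of 0.01. The mixed test of fry, for changes in either direction, passed here too (adjusted p = 0.000738), as it did for many lists. Krt5 and Krt14 differed by -0.02 ± 0.09 and 0.09 ± 0.09, and Sox2, a stem cell transcription factor, changed by -1.25 ± 0.30 as the 1 member that fell, there and adjusted over the list alone. The call of Sox2 was lost on leaving out KR 1, KR 5, KR 6 or KHR 5 (adjusted p up to 0.0751). Among 14 stress keratinocyte genes (mean change 0.27 ± 0.12, adjusted p = 0.63), 1 rose and 1 fell (3 and 1 adjusted over the list alone). The antimicrobial gene Lcn2 rose by 1.69 ± 0.30 (0.95 with the mean over probesets and 1.09 with median polish), and the defensin gene Defb4 changed by -0.48 ± 0.11, which was lost on leaving out any of 6 arrays (adjusted p up to 0.0693).

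Of the immune lists, those of interferon response, macrophages and neutrophils passed. The interferon list had a KR mean of 4.61, below the median level of all genes (4.98), so the size of its change is not exact. Of 34 interferon response genes, 3 rose and none fell (7 higher adjusted over the list alone), and the list mean was 0.32 ± 0.09 higher (adjusted p = 6.26e-06; adjusted p = 0.219 with an estimated correlation). Oasl2, Ifih1 and Eif2ak2, sensors and effectors of double-stranded RNA, rose by 0.75 ± 0.19, 0.80 ± 0.20 and 0.71 ± 0.19, with adjusted p-values of 0.0431, 0.0433 and 0.0489 that rose above 0.05 on leaving out any of 10, 9 and 9 arrays (up to 0.0914, 0.101 and 0.112). Mx1 differed by 0.43 ± 0.12 (adjusted p = 0.0675; 0.00805 without KHR 1 and up to 0.139 without others). Of 15 macrophage genes, 1 rose, also adjusted over the list alone, with a mean change of 0.39 ± 0.15 (adjusted p = 0.00128; adjusted p = 0.298 with an estimated correlation and 0.0652 with fry). That gene, Ms4a7, rose by 1.15 ± 0.29 (0.63 with the mean over probesets; 0.47 and no longer past the threshold with median polish, adjusted p = 0.133), and lost its call on leaving out any of 9 arrays (adjusted p up to 0.0982). Apoe, C1qb and Cd68 differed by 0.61 ± 0.21, 0.58 ± 0.22 and 0.53 ± 0.21, none past the threshold. Of 15 neutrophil genes, 2 rose (3 adjusted over the list alone), the chemokine receptor Cxcr2 by 0.83 ± 0.14 and the gelatinase Mmp9 by 1.04 ± 0.25. Clec4e and Elane differed by 0.58 ± 0.19 and 0.15 ± 0.08 (adjusted p = 0.115 and 0.417). The neutrophil mean was 0.30 ± 0.13 higher (adjusted p = 0.0148; adjusted p = 0.298 with an estimated correlation and 0.0558 with fry), and the call was lost without KR 1, KR 3 or KHR 1 (adjusted p = 0.0549, 0.0600 and 0.0747). Mmp9 lost its call on leaving out any of 8 arrays (adjusted p up to 0.0778) and with the mean over probesets (0.65, adjusted p = 0.0763).

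The other immune lists did not pass. Among 24 inflammatory cytokines and chemokines (mean change 0.20 ± 0.07, adjusted p = 0.0750), Il1a, the epithelial alarmin, rose by 0.81 ± 0.17 (2 members adjusted over the list alone). The list passed without KR 5 or KHR 2 (adjusted p = 0.0423 and 0.0225, and up to 0.322 without others) and with fry (adjusted p = 0.0435). It also passed with array medians subtracted (adjusted p = 0.0499) and with the muscle covariate (adjusted p = 0.0407), but not with an estimated correlation (adjusted p = 0.298). Of 19 antigen presentation genes (mean change 0.06 ± 0.06, adjusted p = 0.534), B2m, the MHC class I light chain, rose by 0.68 ± 0.17, also adjusted over the list alone, and lost its call on leaving out any of 7 arrays (adjusted p up to 0.0875). No member passed in the lists of 24 T and NK cell genes (mean change 0.02 ± 0.04, adjusted p = 0.915), 15 B and plasma cell genes (-0.03 ± 0.02, adjusted p = 0.684), 9 mast cell genes (0.23 ± 0.12, adjusted p = 0.379) and 10 dendritic and Langerhans cell genes (0.01 ± 0.05, adjusted p = 0.583). Adjusted over the list alone, none passed in the first 3 of these lists and 1 in the dendritic list, whose median of -0.05 and test had the opposite sign to its mean. The member that passed so was Epcam, higher by 0.88 ± 0.24 (adjusted p = 0.0670 over all genes). Its KR mean of 10.5 lay far above the list's KR mean of 5.10, so its difference need not come from dendritic cells. Klrk1, the NKG2D receptor gene, differed by 0.28 ± 0.10 (adjusted p = 0.153). The T and NK cell, B and plasma cell and mast cell lists had KR means of 4.33, 4.04 and 4.16. These lay below the median level of all genes (4.98), so with no detection call a change there could have gone unseen.

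The sebaceous gland, skeletal muscle and adipocyte lists passed with the preset correlation, each losing its call with an estimated correlation. The sebaceous gland and adipocyte lists also passed with fry (adjusted p = 0.0248 and 0.00294). Of 10 sebaceous gland genes none passed, 7 were higher adjusted over the list alone, and the mean was 0.68 ± 0.21 higher (adjusted p = 0.00086; adjusted p = 0.219 with an estimated correlation). The lipid enzyme genes Elovl3 and Awat1 differed by 1.69 ± 0.56 and 1.45 ± 0.47 (adjusted p = 0.128 and 0.118), and both passed without KR 3 (adjusted p = 0.0146 and 0.0073; up to 0.243 and 0.226 on leaving out others). Of 30 skeletal muscle genes none passed, also adjusted over the list alone. Their mean was 0.43 ± 0.35 higher (adjusted p = 0.0111; adjusted p = 0.749 with an estimated correlation), and the call was lost without KR 1, KR 6, KHR 4 or KHR 5 (adjusted p = 0.114, 0.0505, 0.0547 and 0.425), where the mean was 0.32, 0.35, 0.35 and 0.21, with array weights (adjusted p = 0.0734) and with fry (adjusted p = 0.496). Without KR 1 and KHR 5 together, the skeletal muscle mean was 0.09 (adjusted p = 0.973). Ryr1, the calcium channel of muscle, differed by 0.98 ± 0.33 (adjusted p = 0.135). Of 12 adipocyte genes 1 fell, also adjusted over the list alone. This was Pparg, a lipid regulator that sebaceous and epithelial cells also express, at -1.27 ± 0.20 (adjusted p = 0.00294). Fabp4 and Lep differed by -0.43 ± 0.15 and -0.27 ± 0.12, and Plin4 by 0.46 ± 0.23, none past the threshold. The adipocyte mean changed by -0.21 ± 0.03 (adjusted p = 0.0148), a call lost with an estimated correlation (adjusted p = 0.102), with median polish (adjusted p = 0.0768) and without the dimmest genes (adjusted p = 0.0641).

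The remaining tissue lists did not pass. Of 20 fibroblast matrix genes 1 fell (2 lower adjusted over the list alone), the collagen gene Col1a2, at -0.80 ± 0.18 (adjusted p = 0.0220; 0.0578 without KHR 4 and 0.0525 without KHR 6). The fibroblast mean differed by -0.05 ± 0.19 (adjusted p = 0.270), and passed without KR 2 or KHR 5 (-0.14 and -0.15, adjusted p = 0.0429 and 0.0425), but was 0.09 without KR 3 (adjusted p = 0.980) and 0.01 without KHR 6. Of 19 invasion and EMT genes (mean change 0.20 ± 0.05, adjusted p = 0.217), 2 rose, also adjusted over the list alone. These were the matrix proteases Mmp3 and Mmp13, by 1.83 ± 0.33 and 0.83 ± 0.14. Of 8 Schwann cell genes (0.30 ± 0.07, adjusted p = 0.379), the transcription factor gene Egr2 rose by 1.87 ± 0.37, also adjusted over the list alone; Egr2 is also an early response gene in other cells. Of 16 hair follicle genes (0.13 ± 0.21, adjusted p = 0.675), Tchh, trichohyalin, rose by 1.07 ± 0.24 (2 members adjusted over the list alone) and lost its call without KR 1, KR 2, KR 3 or KHR 3 (adjusted p up to 0.0615). No member passed, also adjusted over the list alone, among 14 endothelial genes (0.12 ± 0.12, adjusted p = 0.576), 14 salivary gland genes (0.02 ± 0.05, adjusted p = 0.716, with a median of -0.04 and a test of opposite sign) and 2 blood genes (-0.21 ± 0.14, adjusted p = 0.457). The salivary gland and blood lists had KR means of 4.58 and 4.53, below the median level of all genes (4.98), so a change there could have gone unseen. No haemoglobin gene was among the blood genes measured.

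Among metabolic lists, the Nrf2 antioxidant genes passed with the preset correlation (adjusted p = 0.0215) and not with an estimated one (adjusted p = 0.298). Of 15 measured, 1 rose and 3 fell (2 and 4 adjusted over the list alone). Aldh3a1, an aldehyde dehydrogenase, changed by -1.36 ± 0.18 (adjusted p = 0.00113). Gclc and Gclm, which encode the subunits of the enzyme that starts glutathione synthesis, changed by -0.93 ± 0.14 and -0.49 ± 0.10 (-0.31 for Gclm with the mean over probesets). Gsr, glutathione reductase, rose by 0.63 ± 0.12. The list mean changed by -0.20 ± 0.07, and the call was lost without KR 1, KHR 4 or KHR 5 (adjusted p = 0.0523, 0.0547 and 0.0542) with the Xist level as a covariate (adjusted p = 0.0837) and with fry (adjusted p = 0.0555). Of 15 Notch pathway genes, Notch3 and Notch2 fell by 0.59 ± 0.13 and 0.35 ± 0.09 (3 members lower adjusted over the list alone), calls lost on leaving out any of 6 and 9 arrays (adjusted p up to 0.0633 and 0.0938). The Notch list did not pass (mean change -0.11 ± 0.09, adjusted p = 0.0880), but passed without KR 4, KR 5 or KHR 1 (adjusted p = 0.0247, 0.0354 and 0.0416); without KR 1 the mean was -0.05, and the highest adjusted p on leaving out an array was 0.298. Of 24 oxidative phosphorylation genes (0.03 ± 0.02, adjusted p = 0.943, with a median of -0.02), Uqcrc2, of complex III, rose by 0.39 ± 0.10, also adjusted over the list alone, and lost its call on leaving out any of 8 arrays (adjusted p up to 0.0968), with the mean over probesets (0.18, adjusted p = 0.189) and with median polish (0.24, adjusted p = 0.0729). Cox4i1, of the same list, differed by -0.38 ± 0.12 (adjusted p = 0.107). No member passed among 17 hypoxia and glycolysis genes (0.12 ± 0.10, adjusted p = 0.362) and 20 genes of the unfolded protein response (0.09 ± 0.06, adjusted p = 0.392); adjusted over the list alone, 3 hypoxia genes were higher and 1 lower, and none of the unfolded protein response.

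**Figure D3:**
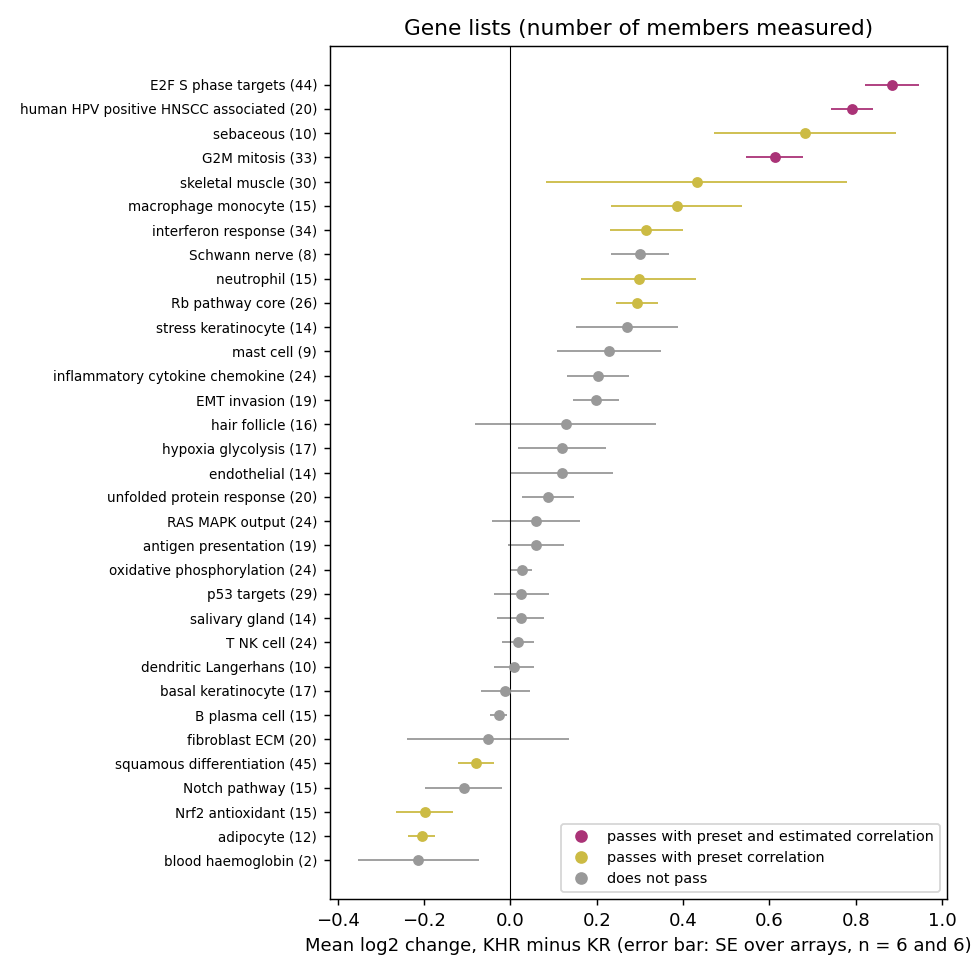
Mean log2 change (KHR minus KR) of the 33 gene lists with the SE over arrays (n = 6 per group) and the number of members measured in parentheses. The E2F, human HPV-positive and G2M lists, at 0.88, 0.79 and 0.61, pass with the preset and the estimated correlation. Another 9 lists pass with the preset correlation and not with the estimated one.

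Of the 71 named genes that passed, 55 passed on leaving out each array in turn. With the Xist level of each array in the model, 15 no longer passed (adjusted p = 0.0516 to 0.103): B2m, Ccnd1, Col1a2, Defb4, Eif2ak2, Ifih1, Mmp9, Ms4a7, Notch2, Notch3, Oasl2, Ppl, Tchh, Tigar and Uqcrc2. The mean of the skeletal muscle list as a covariate ended 14 calls, all among these 15 except Sox2. With the mean over probesets 4 of the 71 no longer passed (Ccnd1, Mmp9, Notch2 and Uqcrc2; adjusted p = 0.0628 to 0.189), with median polish 6 (Col1a2, Ifih1, Mmp9, Ms4a7, Tigar and Uqcrc2; 0.0507 to 0.133) and with quantile normalization 5 (Eif2ak2, Ifih1, Mmp9, Tigar and Uqcrc2; 0.0504 to 0.107). A test per probeset takes for each gene the probeset with the smallest p, and there 14 of the 71 no longer passed (adjusted p = 0.0505 to 0.304) and 9 changed by over 1.5 times as much. These were Zcwpw1 (5.26), Krt13 (-2.68), Pparg (-2.51), Oasl2 (1.57), Cdk2 (1.52), Ifih1 (1.51), Col1a2 (-1.25), Kif2c (1.14) and Gsr (0.97). Among lists that did not pass, the means of the basal keratinocyte, dendritic and Langerhans, salivary gland, and T and NK cell lists changed sign on leaving out single arrays (-0.04 to 0.02, -0.01 to 0.03, -0.01 to 0.05 and -0.01 to 0.04), as did the p53 and oxidative phosphorylation means with quantile normalization (-0.03 each).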

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

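The tests of the Stag3 and Zcwpw1 pair and of a larger share of cycling cells were chosen only after those results were seen, as was the covariate of muscle genes; the other tests were not.

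The number of genes that differed, 863, was set against chance, animal sex and muscle in the sample. Of 100 splits of the 12 arrays into 6 and 6, only the real split (1 of 100) gave as many genes. The highest of the others gave 9, which argues against chance without excluding it. With the Xist level in the model 61.8% of the genes still passed, and with the muscle list mean 63.4%, which argues against either as the whole cause; the 24 largest changes passed under both. Among the 330 genes that no longer passed with Xist, the median size of the change went from 0.59 to 0.55 and the median SE from 0.144 to 0.147, and among the 316 with muscle from 0.58 to 0.53 and from 0.140 to 0.146, so calls ended with a slightly smaller change and a slightly larger error. The HPV transgene is a candidate explanation that stays open beside litter, age and batch, which the labels do not give.

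The number of lists that shifted, 12, was reached by 4 of 100 splits, the real one included, a share under 0.05, but the highest of the others gave 14, so chance is argued against and not excluded. The other 3 all held 4 arrays of one genotype in a group. The 45 splits into 3 and 3 of each genotype hold no genotype contrast, yet gave up to 9 lists. The preset correlation can thus call lists on these arrays without such a contrast. Lists that passed with it and not with an estimated correlation are therefore weaker evidence. The 3 lists that passed with an estimated correlation were reached by 1 of 100 splits, the real one. The highest of the others gave 1, which argues against chance for that number without excluding it.

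Stag3 and Zcwpw1 lie near each other in the order of genes of the assembly GRCm38.p6 and rose with little spread between arrays. Strain variants under single probes are argued against, since 66.7% of the probesets below the median change of their gene (12 of 16 and 4 of 8), whose rise the choice of these genes does not fix, had all KHR arrays above all KR arrays, against 1.09% of all probesets. An effect that raised the whole neighbourhood is argued against as well. The 23 genes between Stag3 and Zcwpw1 had a median change of 0.00 and an upper quartile of 0.33, with 2 that rose, Mcm7 and Cops6. With 20 genes more on each side 3 of 63 rose, the other being Gpc2, by 0.91 ± 0.16. Gpc2 is the first gene outside the interval on its side. Taf6, inside it, differed by 0.40 (adjusted p = 0.0582). Cops6, Gpc2 and Taf6 were chosen after their values were seen. A rise of only part of the neighbourhood is not argued against by these values. Variant or passenger DNA acting on Stag3 and Zcwpw1, or also on some genes near them, cannot be told apart from an effect of the transgene. All 6 KHR arrays showed the rise of Stag3 and Zcwpw1 and would all carry such DNA. The transgene stays open as the biological explanation.

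The E2F list rose more than the G2M list, by 0.27 ± 0.05 (SE, n = 6 each; exact permutation p = 0.0021645, two-sided, the smallest it can give). A larger share of cycling cells stays open as a cause, since that difference is itself the observation and does not test it. With the G2M mean of each array in the model the group term of the E2F mean was 0.46 ± 0.14 (SE), but 0.35 ± 0.18 without KR 4, within 2 SE of 0. Brighter probes responding less is argued against, because the difference was 0.29 ± 0.07 with the mean level of each gene in a regression across genes, which are not independent replicates. An effect of the transgene on E2F targets may explain it, as a hypothesis found and tested on the same data, and a change in the share of S-phase among cycling cells was not tested.

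Of 318 groups of 6 arrays examined, 17 held an array far from the others, where chance gives about 1 in 20. In KR tumours, Stag3 was highest on KR 4 at 4.58 against 4.24 to 4.37 on the other KR arrays. Ina was lowest on KR 1 at 3.76 (others 4.39 to 4.64), and Zcwpw1 was lowest on KR 4 at 4.31 (others 4.72 to 4.89). Fmo2 was highest on KR 6 at 7.77 (others 6.77 to 7.09), Pax9 on KR 1 at 9.001 (others 7.39 to 7.98), Ms4a7 on KR 3 at 6.25 (others 5.06 to 5.49) and Eno3 on KR 5 at 7.85 (others 7.04 to 7.25). Defa-ps12 was lowest on KR 3 at 9.88 (others 10.1 to 10.3), and Cdkn2a was lowest on KR 4 at 4.84 (others 6.25 to 6.98). The component 2 score of KR 1 was 21.1 against -19.5 to -6.48 on the other KR arrays.

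In KHR tumours, Zcwpw1 was lowest on KHR 2 at 7.65 (others 8.02 to 8.18), Prim1 was highest there at 9.43 (others 8.997 to 9.16) and Ccne1 lowest at 7.29 (others 7.76 to 8.01). Bpifa5 was highest on KHR 3 at 5.39 (others 3.90 to 4.38), and Kdr was highest on KHR 4 at 7.21 (others 6.59 to 6.82). On KHR 5, Cdh3 was lowest at 8.97 (others 9.45 to 9.60), and the mean of the mast cell list was highest at 4.73 (others 4.22 to 4.41).

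Among the 35998 probesets without a single gene symbol, which no comparison used, 125 differed between the groups (limma, adjusted over all probesets), 70 of them higher and 55 lower. That is 0.347%, against 0.966% of the probesets with 1 symbol. Probeset 17549141 rose from 4.00 to 11.8, a change of 7.76 ± 0.14 (SE; adjusted p = 2.1e-11). Probeset 17230065 changed by -3.18 ± 0.34, from 10.5 to 7.29 (adjusted p = 0.00105). What either measures was not analysed here.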

How the results depend on the processing

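The muscle covariate, animal sex as a factor, leaving out KR 1 and KHR 5 together, and the HPV-positive list without E2F members or Stag3 were chosen after the data were seen; the other alternatives were planned. The values carry no detection call, so dim genes have no background bound. The cause of each change below was not tested, except where a stricter threshold or fewer arrays made it. Against 863 genes, 625 higher and 238 lower, the mean over probesets gave 1445 (973 higher, 472 lower) and median polish 425 lower of 1226. A test per probeset gave 431 lower of 1144, and quantile normalization 365 lower of 845, with 56.8% higher against 72.4%. Of the 863 genes, these settings kept 703, 650, 513 and 710, in that order. The Xist covariate gave 555 (416 higher, 139 lower; 533 of the 863 kept), sex as a factor 526 (393 and 133; 505 kept), the muscle covariate 137 lower of 623 (547 kept) and leaving out KR 1 and KHR 5 144 lower of 616. At least 1.5-fold left 140 lower of 603, and adjusted p under 0.01 left 312 (249 and 63). The exact rank permutation test gave 0 genes, 0 higher and 0 lower, with a smallest adjusted p of 0.0809, 3051 genes at an unadjusted p under 0.05 and 618 at the smallest p it can give. Those 618 were too few for any gene to pass after adjustment over 23102 genes, so the 0 does not decide on the calls. Leaving out each array in turn gave 523 to 1085 genes, 400 to 797 higher and 123 to 288 lower, lowest without KHR 4 and KR 2, and a share of 0.65 to 0.84 for component 1. The lists fell from 12 to 3 with an estimated correlation; fry called 8, of which 7 were among the 12. The E2F, G2M and HPV-positive lists passed in every setting run.

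The replicate number as a block gave 925 genes (698 kept) and 13 lists, bringing the inflammatory list past the threshold (adjusted p = 0.0414). Under the block Defb4, Notch2, Oasl2, Sox2 and Uqcrc2 no longer passed (adjusted p = 0.0541 to 0.0859). Same-numbered arrays correlated at -0.003 to 0.234 and 3 of 12 arrays correlated best with their own number, and as not every pair was above 0.1 the numbers were not taken to pair the samples.

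No named gene that passed reversed in any setting. Over 122 named genes and the 29 settings that test genes, not every gene in each, 3117 values kept their side of the threshold, 314 lost it, 69 gained it and 24 reversed, all in genes that did not pass: with the mean over probesets Gjb1 (-0.0245), Slc4a1 (-0.00892) and Cdkn1a (-0.0712); with median polish Cdkn1a (-0.0272); with quantile normalization Mdm2 (-0.0205) and Krt5 (0.0557); with array medians subtracted Mdm2 (-0.000828); with the muscle covariate Mdm2 (-0.0513); without KR 1 and KHR 5 Mdm2 (-0.0517) and Krt5 (0.0317); and per probeset Mx1 (-0.44), Pdcd1 (-0.34), Cd79a (-0.38), Smr3a (0.24) and Cdkn1a (-0.40). Leaving out each array in turn, Mdm2 ranged from -0.0560 to 0.144, Krt5 from -0.0631 to 0.00713 and Slc4a1 from -0.0205 to 0.197. The planned log2(value + 16) was not run, since the values were already logarithms.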

Other observations

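The germline list, its tests and the families of genes below were chosen only after values had been seen.

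A list of 52 genes of meiosis and the germ line was compiled after the rise of Stag3, Zcwpw1, Tdrd1 and Rbm46 had been seen, so it is not independent evidence. Of these genes 9 rose, none fell and 43 did not pass; the median change was 0.06, and a test that includes the 4 genes restates what prompted it (camera p = 2.63e-05; p = 0.000422 with an estimated correlation). Without them, 5 of 48 rose, the median change was 0.05 and the p-values were 0.0241 and 0.0211, not adjusted for having chosen the list. Besides those 4, Syce2, of the synaptonemal complex, rose by 1.82 ± 0.14, Piwil2, of the piRNA pathway, by 1.498 ± 0.23, Iho1, of meiotic break formation, by 1.22 ± 0.15, the cohesin gene Smc1b by 0.70 ± 0.13 and Terb1, of meiotic telomeres, by 0.55 ± 0.14 (SE). In KR tumours, 47 of the 52 lay below the median level of all genes.

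Genes were also grouped by the stem of their symbol, giving 340 families with at least 8 members. Genes that rose were over-represented in 4 families (Fisher's exact test, one-sided, adjusted over the families): Mcm (7 of 10, adjusted p = 3.9e-07), with Mcm2 to Mcm7 of the replicative helicase and Mcm8, which is not part of it, Nup, of the nuclear pore (8 of 21, adjusted p = 6.96e-06), Kif, of the kinesins (9 of 38, with 1 that fell, adjusted p = 6.72e-05) and Casp (4 of 9, adjusted p = 0.0051), with 3 caspase genes and Casp8ap2, which shares the stem but encodes no caspase. The test treats genes as independent draws, which members of a family are not, so its p-values do not measure the spread between tumours. Mcm2 to Mcm7 are also in the E2F list, and Kif11, Kif20a and Kif2c in the G2M list, so these families partly restate those lists. Genes that fell were over-represented in 1 family, Ces, of the carboxylesterases (5 of 20, adjusted p = 0.000517), whose near-identical copies can share probes.

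Cdkn2a had 7 probesets, and the 4 with KR means above 6 differed by -0.47 to -0.87, none past the threshold after adjustment (lowest adjusted p = 0.124). The other 3, with KR means of 3.30 to 4.77, differed by 0.22, 0.03 and 0.02. Which exon each probeset measures was not analysed here. The upper quartile of all probesets per array was 8.20 ± 0.03 in KR tumours and 8.25 ± 0.04 in KHR tumours (SD, n = 6 each; exact permutation p = 0.0498, two-sided).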
